A study of Arabidopsis thaliana with 6 samples.

How the data were processed

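Seedlings of Arabidopsis thaliana Col-0 were sampled at 9 days in 3 genotypes, WT, nerd-1 and cpsf30-1, with 2 libraries each. Per the labels, RNA was treated with DNase on the extraction column, and a service company made stranded polyA libraries that were sequenced as pairs of 125 bases, with 37 to 53 M reads per library. Per the submitters' processing notes, the authors used Bowtie2 2.3.4, TopHat2 2.0.7, Cufflinks 2.2.1, Cuffdiff and the TAIR10 build. The counting tool, its strand setting and its handling of overlapping genes are not given in the sources used here. The deposited values are raw counts per transcript, taken per the file names in the 500 bases past its 3' end, and no normalisation by the authors was applied to them. A window carries the name of the gene upstream, and transcripts of a gene can repeat the same reads: of isoform pairs with the same end in the reference, 2313 have identical counts in every library and 348 do not.

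The tables hold 39087 transcripts of 31109 genes. For each gene the transcript whose 3' end lies farthest downstream was kept, with ties to the lowest isoform number, never from counts. Window positions were rebuilt from the gene models of the TAIR10.1 reference, which matched 38527 transcripts and left 560, and all transcripts of 491 genes, without a position. The positions are approximate, since 2309 of 4622 pairs of isoforms with identical counts have different ends in the reference. Windows were classed as isolated (13927 genes, no other annotated gene on either strand), other strand (9651, only genes on the other strand) or same strand (7040, another gene on the same strand). Some isolated windows overlap a longer isoform of their own gene, and 1679 of the 1932 tested do not. Totals with 1 transcript per gene were 8703050 and 13740648 in WT, 9774817 and 9764394 in nerd-1, and 10207122 and 11291784 in cpsf30-1. CPM of windows use the tested counts scaled by TMM, and the bounds use the same scale, while the floors given per library use the totals before scaling.

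Counts were tested in edgeR 4.0.16 with limma 3.58.1 under R 4.3.3, on the deposited counts. Low windows were removed by the edgeR filter for expression, which left 14151 tested and 16958 not tested. Libraries were scaled by TMM, with factors from 0.958 to 1.05. A quasi-likelihood F-test, two-sided, was fitted to all 6 libraries with 1 mean per genotype, giving 3 residual degrees of freedom, 4.28 prior degrees of freedom and a common biological coefficient of variation of 0.265. Calls are Benjamini-Hochberg adjusted p under 0.05 within a comparison. Errors after ± are SD over 2 libraries, and SE belongs to the log2 fold change. Classes and gene lists were tested with camera on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the classes or lists of a comparison, and again with a correlation estimated from the data. Enrichment of calls among isolated windows used a two-sided Fisher's exact test. Folds against a group at 0 counts in both libraries are bounds computed with 3 counts per library. With 1 to 3 counts in a group the ratio is given with its 95% exact counting interval.

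The comparisons, tests, lists, naming rule and alternatives were fixed before the data were examined, apart from what is named here as added. The rule names, among calls with a mean CPM of at least 2 in the higher group and both mutant libraries on the same side of both WT libraries, the 8 largest changes in each direction among isolated windows and the 4 largest among others. For cpsf30-1 against nerd-1 it names 4 in each direction. It adds up to 3 members per list with the smallest adjusted p, and NERD and CPSF30 always. The windows past GUN5, AT3G60750, D-CDES, AT4G19830, GGT1, AT5G59250 and AT5G51110, and those past LHCA2, RBCS3B, LHCA1 and AT1G73460, fall outside the rule and were chosen after their values were seen. The 14 lists were polyadenylation machinery (30 genes), m6A writers, readers and erasers (21), RNA silencing and DNA methylation (34), oxidative stress and detoxification (21), salicylic acid defence (18), NLR immune receptors (25), nitrate response (17), flowering time (14), photosynthesis (19), circadian clock (11), heat shock (9), cold and abscisic acid response (11), auxin response (12) and root markers (10). The reading of lists from windows that lie on their genes' exons by at least 250 bases was added later.

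The alternatives fixed in advance were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals without TMM, TMM from same-strand windows, no filter, a stricter filter, a fit of only the 4 libraries compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.01, a 2-fold minimum, the transcript with the highest total, all deposited transcripts, an estimated correlation, fry and classes from 1000 bases. Alternatives added later left out the windows in runs, exchanged the replicate numbers of cpsf30-1 in the block, and dropped isolated windows overlapped by a longer isoform. A further one left out each library on the 14151 windows tested with all 6, since with 5 libraries the filter passes 15311 to 15896. The replicate numbers as given do not pair the samples. Deviations of replicate 1 from its group mean correlated across windows with r = -0.0049 between WT and nerd-1 and -0.001 between the mutants. Between WT and cpsf30-1 the correlation was -0.311 (Spearman's rho -0.437). There replicate 1 of WT deviated like replicate 2 of cpsf30-1, so a factor shared by these groups with crossed numbers is not excluded. Its source was not tested.

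A run was defined as at least 8 neighbouring windows with a minimum count of 10 or more and at least 4 of them within 5% of that minimum. Chloroplast and other location notes of the reference annotation were tested with 10000 random lists matched on the mean CPM of the window in 10 bins. The fit was tested on simulated data with 100 changed windows of each size. Of 2-fold changes it recovered 4, 9 and 9 of 100, and of 4-fold changes 61, 62 and 53, for nerd-1 against WT, cpsf30-1 against WT and cpsf30-1 against nerd-1, with 11, 8 and 11 false calls. Overlap of the mutants was compared with 50 simulations that share the WT libraries and hold no effect of either mutant. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures. Raw reads and expression over whole genes were not used here.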

Results

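The counts cover the 500 bases past the annotated 3' end of each transcript in 9-day-old Arabidopsis thaliana seedlings of the Col-0 ecotype. The libraries came from the wild type (WT), from nerd-1 and from cpsf30-1, with 2 libraries per genotype. CPSF30 is a subunit of the complex that cleaves and polyadenylates mRNA, and NERD acts in silencing guided by small RNAs and in DNA methylation. A window is named after the gene it follows, and its reads may come from a neighbouring gene, so a gene said to rise or fall stands for the reads of its window and not for its expression. Total counts over all deposited windows were 11793952 and 18569498 in WT replicates 1 and 2, 13353807 and 13301722 in nerd-1, and 13973971 and 15382351 in cpsf30-1. A count of 0 in a library allows a level of up to 0.218 to 0.345 CPM (counts scaled by the library total with 1 transcript per gene), from 3 counts of that total. Such floors and all intervals given here cover counting error only. Of 31109 genes, 13927 had a window free of any other annotated gene on either strand, called isolated here. These isolated windows were 44.8% of the windows and held 5.72% of the counts. The median of the mean count was 75.5 in windows whose neighbour lay on the other strand and 37.2 where it lay on the same strand, so the values behave as counts of both strands. The WT pair differed most, with an SD of the log2 difference between its libraries of 0.856, against 0.570 in nerd-1 and 0.666 in cpsf30-1. Nothing in the labels says that replicates came from separate plants or cultures, so the p-values measure the spread between these samples, which may be technical. Without 1 library the edgeR filter let 15311 to 15896 windows be tested instead of 14151, so those fits change the library and the windows together. The same 14151 windows were therefore also tested without each library, as an alternative chosen after the data were seen, and are called the common windows here.

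In every library some stretches of neighbouring windows shared 1 minimum count. The longest lay in WT replicate 1 on chromosome 1, from 10046776 to 10474655 in the TAIR10 build, where 115 windows from AT1G28590 to the light-harvesting gene CAB2 had a median count of 1487. The medians of the same windows in the 5 other libraries were 9 to 19. Such runs held 1025 windows in at least 1 library. They included 43 of the 1453 windows called in cpsf30-1 against WT, 61 of the 1503 called in cpsf30-1 against nerd-1, and 0 of the 6 called in nerd-1 against WT.

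**Figure D1:**
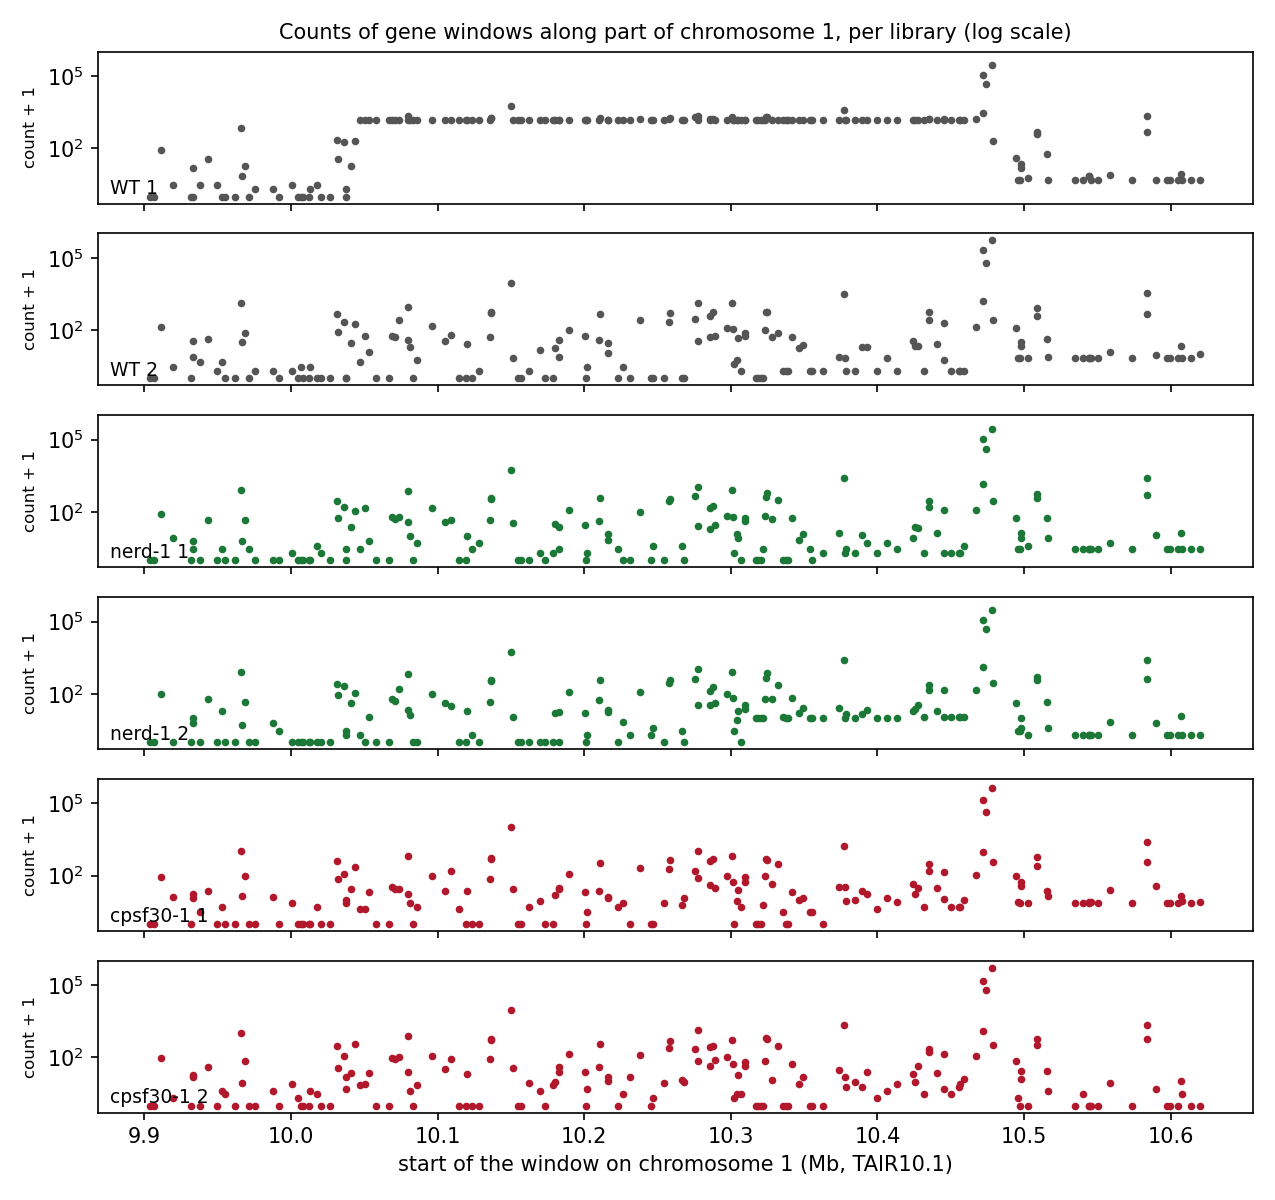
Count plus 1 (vertical axis, log scale) of each window along chromosome 1 between 9.9 and 10.6 Mb (horizontal axis), with 1 panel per library. In WT replicate 1 the windows of the run share a floor of 1475 counts, which no other library has.

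Reads of CPSF30, the gene mutated in cpsf30-1, fell in that line in 1 window. The window past the shorter transcript AT1G30460.2, at 10770686 to 10771185 on chromosome 1, lies partly in the longer transcript and partly past its end. It also overlaps AT1G30455 on the other strand. It held 43 and 49 counts in WT, 66 and 58 in nerd-1, and 1 and 0 in cpsf30-1. The ratio of WT to cpsf30-1 was 87.8 with a 95% counting interval of 15.4 to 3504 (log2 fold change -6.20, SE 0.753, adjusted p = 0.00538, n = 2 per group, in the fit of all deposited windows). The window past the longer CPSF30 transcript held 2 to 16 counts, too few to pass the edgeR filter, so it was not tested. The window past NERD (AT2G16485) held 0 counts in 5 libraries and 3 in cpsf30-1 replicate 1, so the data cannot check the nerd-1 lesion.

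The comparison of cpsf30-1 with WT asks how loss of this polyadenylation factor changes reads past gene ends. In cpsf30-1, reads rose in isolated windows past many genes. The window past GUN5 (AT5G13630, the H subunit of magnesium chelatase in chlorophyll synthesis), at 4386807 to 4387306 on chromosome 5, held 67.6 ± 11.7 CPM in cpsf30-1 against 0.753 ± 0.105 in WT and 1.61 ± 0.21 in nerd-1 (SD, n = 2 each). That was 87.4-fold above WT (log2 fold change 6.45, SE 0.319, adjusted p = 0.000726). Past the transketolase gene AT3G60750 reads rose 40.7-fold, past D-CDES (a D-cysteine desulfhydrase) 22.2-fold, and past GGT1 (a photorespiratory aminotransferase) 27.9-fold, with adjusted p of 0.000726, 0.000757 and 0.00209. The window past APX1, which encodes the cytosolic ascorbate peroxidase, rose 20.4-fold (14.8 ± 2.04 against 0.697 ± 0.185 CPM, SE 0.372, adjusted p = 0.00224). These windows and those past AT4G19830 (18.6-fold), AT5G59250 (8.30-fold) and AT5G51110 (14.1-fold) kept their calls with any 1 library left out, but AT3G60750 lost its call when the transcript with the highest total was used (log2 fold change 0.62, adjusted p = 0.135).

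**Figure D2:**
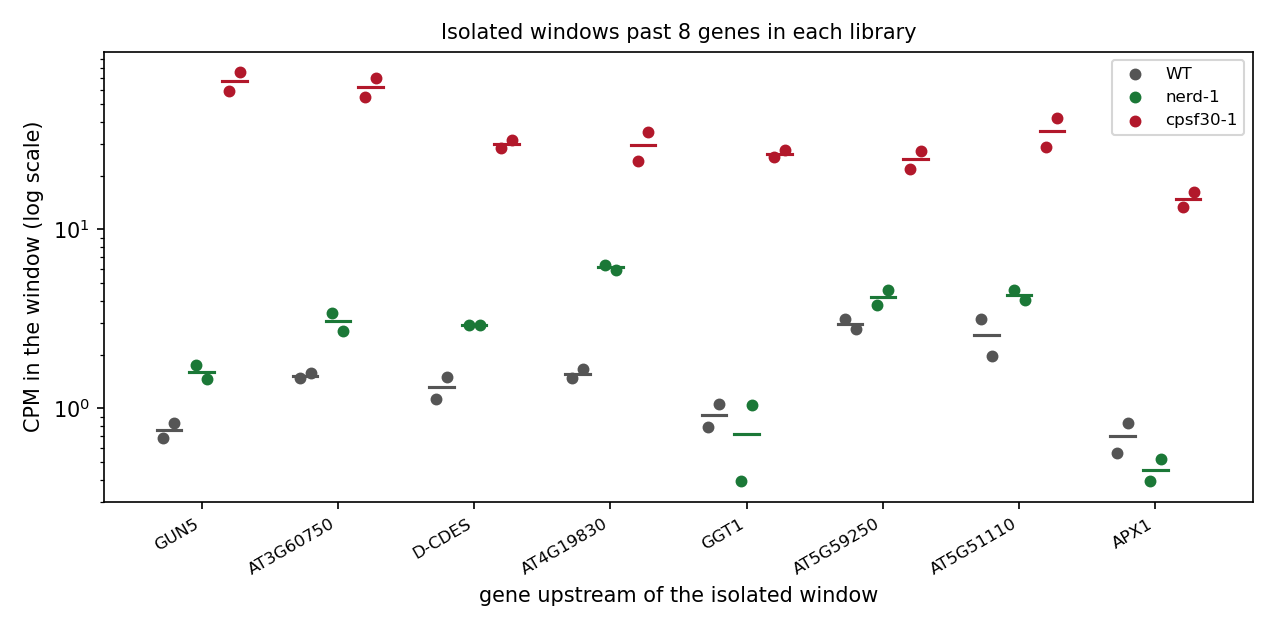
CPM (vertical axis, log scale) of each library, grouped by genotype, in 8 isolated windows, with bars at group means. In each of the 8 windows both cpsf30-1 libraries lie above the 4 others, as past GUN5 with group means of 67.6 CPM in cpsf30-1 and 0.753 in WT.

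Over all 14151 windows tested, 1049 rose and 404 fell in cpsf30-1 against WT (edgeR, adjusted p under 0.05), and 3919 had an unadjusted p under 0.05. At least 4-fold changes were 700 of the higher and 61 of the lower calls. Among the 1932 isolated windows tested, 301 rose and 34 fell, which is 15.6% and 1.76%. All isolated windows were 13927, with a median of the mean count of 0.5, and most did not pass the filter. A window near 0 can pass it by being high in 1 genotype, so these shares and the odds ratios that follow depend on the filter. The shift of the isolated windows given below rests on the same filtered windows. The 301 had a median fold change of 11.7, or 9.09 with the 35 windows at 0 in WT set to their bound, and 12 of them lay in runs. Isolated windows were called higher more often than others (Fisher's exact test, odds ratio 2.83, 95% interval 2.44 to 3.27, p = 1.94e-40), with an odds ratio of 2.26 without cpsf30-1 replicate 1 to 3.26 without nerd-1 replicate 2 on the common windows. With the 2607 to 2916 isolated windows that the filter let through when 1 library was left out, it was 1.51 without WT replicate 2 to 2.04 without nerd-1 replicate 1. They were called lower less often (odds ratio 0.574, interval 0.390 to 0.819, exact p = 0.00119), but of the fits with 1 library left out only that without WT replicate 1 kept this (odds ratio 0.410, exact p = 7.68e-05, and 0.559, exact p = 0.00363, on the common windows). The ratio was 1.13 (exact p = 0.362) without WT replicate 2, where 81 isolated windows fell and 55 of them lay in runs. It was 1.03 (exact p = 0.882) and 0.944 (exact p = 1) without nerd-1 replicates 1 and 2, and 0.681 (exact p = 0.479) and 0.587 (exact p = 0.283) without cpsf30-1 replicates 1 and 2. These 5 fits gave, on the common windows, 0.895 without cpsf30-1 replicate 2 to 1.11 without WT replicate 2 (exact p 0.449 to 0.9). Neighbouring windows are not independent, so these exact p-values may be too small. The median and mean log2 fold change were 0.50 and 0.87 in isolated windows, -0.06 and 0.05 in windows with a gene on the other strand (338 higher and 225 lower calls), and -0.03 and 0.20 in those with a gene on the same strand (399 and 137), so median and mean differ in sign in the last 2. The shift of the isolated windows passed camera (adjusted p = 1.74e-07, and adjusted p = 0.0293 with an estimated correlation), while camera placed the other-strand windows below the rest (adjusted p = 0.0263, lost at adjusted p = 0.101 with an estimated correlation) although more of them were called higher than lower. Leaving out 1 library kept the isolated shift past the threshold, with medians on the common windows from 0.472 without cpsf30-1 replicate 1 to 0.655 without WT replicate 1. Over the more numerous windows that the filter let through, the medians were 0.437 to 0.997 without the same libraries. With the filter on the libraries kept, the 1453 calls became 339 without cpsf30-1 replicate 1 and 236 without replicate 2, 763 and 924 without WT replicates 1 and 2, and 488 and 502 without nerd-1 replicates 1 and 2. The 301 became 68 and 49 without cpsf30-1 replicates 1 and 2, 145 and 126 without WT replicates 1 and 2, and 124 and 125 without nerd-1 replicates 1 and 2. Calls on the common windows were 506 and 479 without cpsf30-1 replicates 1 and 2, 1149 and 1159 without WT replicates 1 and 2, and 817 and 819 without nerd-1 replicates 1 and 2, with 105, 94, 248, 180, 219 and 221 isolated windows higher in the same order.

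**Figure D3:**
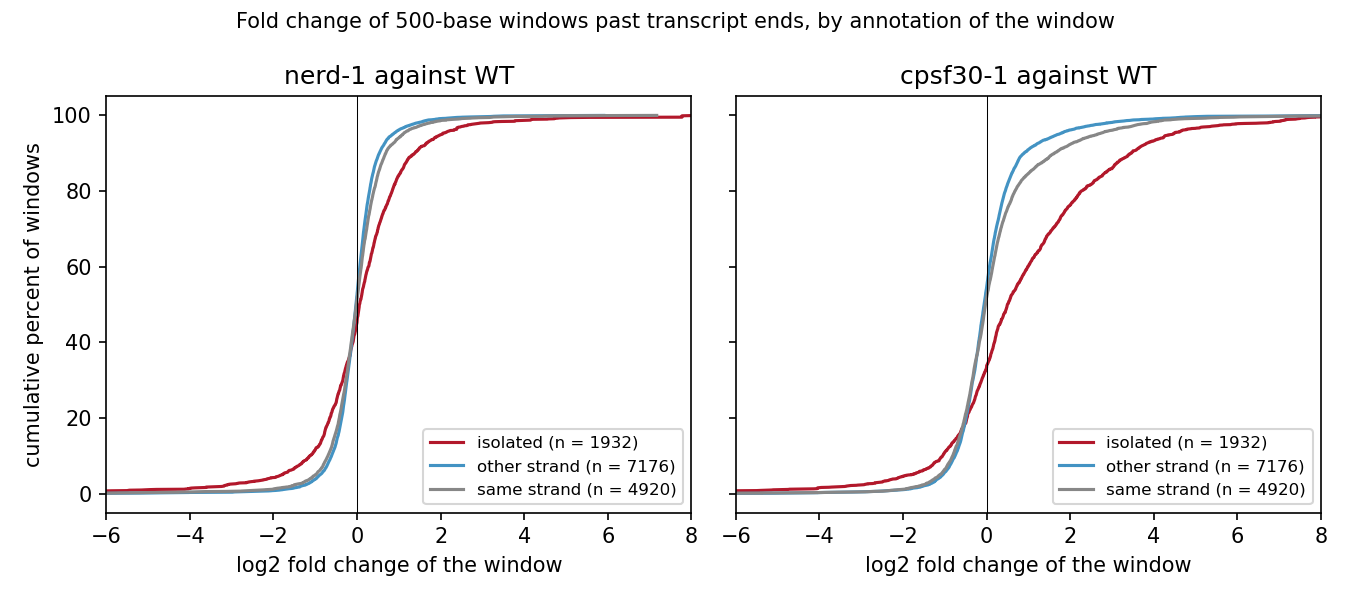
Cumulative percent of tested windows (vertical axis) by log2 fold change against WT (horizontal axis), for nerd-1 and cpsf30-1, with lines for isolated windows (1932), windows with a gene on the other strand (7176) and on the same strand (4920). In cpsf30-1 the isolated line lies to the right of the others, with 66.4% of isolated windows above 0 against 54.1% in nerd-1.

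The 8 isolated windows ranked highest by fitted fold change were at 0 counts in both WT libraries, so their folds are bounds. The window past AT4G22240, a plastid fibrillin, rose at least 29.3-fold to 8.29 ± 0.09 CPM (adjusted p = 0.00496), and that past the pseudogene AT4G04635 at least 27.0-fold (adjusted p = 0.00484). AT4G04915, on the other strand, lies 5 bases beyond the window past AT4G04635, so its reads may reach that window. Increases of at least 20.5-fold past ATX1 (a copper chaperone), 17.5-fold past AT5G44575 and 16.0-fold past F3H (flavanone 3-hydroxylase of flavonoid synthesis) had adjusted p of 0.011, 0.00859 and 0.0081. Those past J11 (a DnaJ chaperone), ELP (extensin-like) and TAR2 (tryptophan aminotransferase in auxin synthesis) were at least 13.3, 12.3 and 11.4-fold, with adjusted p of 0.016, 0.0187 and 0.0134. Of these 8, 6 lost their call without cpsf30-1 replicate 1 (adjusted p 0.0702 to 0.118), and all but AT4G04635 lost it without replicate 2 (0.0502 to 0.127). J11, ELP and TAR2 lost it without WT replicate 2 (0.0552 to 0.0712), ELP without WT replicate 1 (0.0551), and TAR2 without nerd-1 replicate 1 (0.0513) or 2 (0.0504). J11, ELP and TAR2 lost it on the common windows without either cpsf30-1 library and ATX1 without replicate 1 (0.0564 to 0.0778), and 0 of the 8 without a WT or nerd-1 library.

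Of the 1932 isolated windows 34 fell in cpsf30-1, and of the same windows 69 fell without WT replicate 2, 26 without WT replicate 1, 19 without either nerd-1 library, and 14 and 16 without cpsf30-1 replicates 1 and 2. Of the 2607 to 2916 isolated windows that the filter let through in these fits, 81, 18, 14, 7 and 6 fell in the same order. The window past AT5G37890, a RING domain protein gene, fell 9.96-fold (1.18 ± 0.30 against 11.9 ± 1.41 CPM, SE 0.304, adjusted p = 0.00267), and that past EMB2770, a splicing factor-like gene, fell 7.17-fold (1.34 ± 0.71 against 9.58 ± 1.87 CPM, adjusted p = 0.0089). The window past EMB2770 overlaps a longer transcript of EMB2770 itself in the reference. Both kept their calls with any 1 library left out. Past PDF1.2b, a jasmonate-responsive defensin gene, the ratio of WT to cpsf30-1 was 89.99 (95% counting interval 30.5 to 439, adjusted p = 0.00691), with 11.6 ± 8.66 CPM in WT. Ratios past DIN11 and AT4G04630 were 45.8 (7.83 to 1846) and 18.1 (5.90 to 90.5), with adjusted p of 0.0276 and 0.0308. The windows past SPA2, HB4 and AT5G20660 fell 9.73, 8.01 and 7.65-fold, with adjusted p of 0.0222, 0.0253 and 0.025. Their sizes rest on few counts, and AT4G11120 on the same strand lies 27 bases beyond the window past SPA2. The log2 fold change of HB4 (-3.001) was -2.40 without WT replicate 2, -4.32 without cpsf30-1 replicate 1 and -2.39 without replicate 2. That of EMB2770 (-2.84) was -3.52 without cpsf30-1 replicate 1. The ratio past SPA2 was 15.3 (4.07 to 129) without cpsf30-1 replicate 1 and that past AT5G20660 15.2 (4.04 to 128) without replicate 2, each from 2 counts. Without WT replicates 1 and 2 the ratio past PDF1.2b was 124 (42.1 to 608) and 38.2 (12.3 to 192), from 3 counts in cpsf30-1. The window past DIN11 was at 0 counts without cpsf30-1 replicate 1, at least 7.44-fold lower, and without replicate 2 the ratio was 22.4 (3.84 to 903) from 1 count. Of the 8 windows, 4 lost their call without WT replicate 1 (adjusted p 0.0585 to 0.105), 5 without WT replicate 2 (0.059 to 0.102), 5 without nerd-1 replicate 1 (0.0674 to 0.0974) or 2 (0.0577 to 0.0941), 5 without cpsf30-1 replicate 1 (0.0658 to 0.16) and 6 without cpsf30-1 replicate 2 (0.0661 to 0.152). In the fits on the common windows, 1 lost it without WT replicate 1, 2 without WT replicate 2 or either nerd-1 library, and 4 and 5 without cpsf30-1 replicates 1 and 2.

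Windows that overlap another gene also changed in both directions. The window past UGT75B1, a UDP-glucosyltransferase gene, rose at least 86.7-fold from 0 counts in WT (24.5 ± 0.26 CPM, adjusted p = 0.00147), and it also overlaps a longer transcript of UGT75B1 itself. The window past CYP72A8, which lies on CYP72A9, rose at least 32.1-fold (adjusted p = 0.00346), that past ABCG22, a transporter gene, at least 25.8-fold (adjusted p = 0.00506), and that past AT5G35690 at least 24.04-fold (adjusted p = 0.00484). The window past AT4G13572 fell 48.7-fold (0.379 ± 0.011 against 19.1 ± 3.58 CPM, SE 0.336, adjusted p = 0.000757), and that past RTFL18, which lies on GEX3, fell 14.7-fold (adjusted p = 0.00613). The window past AT2G39040, which lies on NATA1, fell 14.8-fold (adjusted p = 0.02), and past NOF1, a nucleolar factor gene, the ratio was 23.5 (7.74 to 117, adjusted p = 0.0237). Both lost their call without nerd-1 replicate 1 (adjusted p 0.0746 to 0.0929), nerd-1 replicate 2 (0.0708 to 0.0888) or cpsf30-1 replicate 2 (0.0522 to 0.0998), AT2G39040 also without WT replicate 2 (0.0638), and NOF1 without WT replicate 1 (0.0791) or cpsf30-1 replicate 1 (0.0518). AT2G39040 kept its call throughout on the common windows, and NOF1 lost it without nerd-1 replicate 1 (0.0549) or 2 (0.0541) or cpsf30-1 replicate 2 (0.0784). Without cpsf30-1 replicate 1 the ratio past AT2G39040 was 105 (18.6 to 4155) from 1 count, and NOF1 was at 0 counts, at least 12.8-fold lower. Without replicate 2 the log2 fold change of AT2G39040 (-3.89) was -3.07, and the ratios past NOF1 and RTFL18 were 11.5 (3.79 to 57.1) from 3 counts and 22.6 (6.10 to 190) from 2.

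Of 14 gene lists, photosynthesis passed in cpsf30-1 against WT. Of its 18 windows tested, 6 rose and 0 fell, or 8 and 1 adjusted over the list alone, and 14 of 18 lay above 0. The median log2 fold change was 0.60 and the mean 1.27 (camera adjusted p = 0.00502, adjusted p = 0.43 with an estimated correlation). Of the 18 windows 10 were isolated, a class with a median of 0.50 in this comparison. Camera compared the list with all other windows, so it cannot tell a shift of the list from that of isolated windows. The windows past PSAF and PSAD-1, photosystem I subunits, rose 5.33-fold (SE 0.253, adjusted p = 0.00381) and 3.45-fold (SE 0.244, adjusted p = 0.00735), and lie on LBD4 and AT4G02760. The window past LHCA3, a light-harvesting gene, rose 7.90-fold (adjusted p = 0.0111) on the pseudogene AT1G61665, but the transcript of LHCA3 with the highest total had a log2 fold change of -0.11 (adjusted p = 0.817). The windows past LHCA2 (29.7-fold, adjusted p = 0.0132), RBCS3B of the Rubisco small subunit (19.04-fold, adjusted p = 0.0158) and LHCA1 (8.70-fold, adjusted p = 0.0212) rose as well. PSAF and PSAD-1 kept their calls with any 1 library left out. LHCA3 (adjusted p 0.0702 and 0.0726), LHCA2 (0.0798 and 0.0877), RBCS3B (0.124 and 0.131) and LHCA1 (0.128 and 0.0959) lost theirs without cpsf30-1 replicate 1 or 2. RBCS3B also lost it without WT replicate 1 (0.0834) or 2 (0.0712), and LHCA1 without nerd-1 replicate 1 (0.0735) or 2 (0.0711). These 4 lost it on the common windows only without a cpsf30-1 library (0.0522 to 0.0984). Without WT replicate 1 the ratio past LHCA2 was 174 (31.05 to 6914) from 1 count in WT, and the log2 fold change of LHCA1 (3.12) was 2.48. Without WT replicate 2 the log2 fold changes of LHCA2 (4.89) and LHCA3 (2.98) were 3.79 and 3.59, and the ratio past LHCA1 was 25.3 (8.51 to 124) from 3 counts.

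Members of other lists changed singly in cpsf30-1 against WT. Of 10 windows of oxidative stress and detoxification, 3 rose and 0 fell, or 3 and 1 adjusted over the list alone (median log2 fold change 0.75, camera adjusted p = 0.277). They were APX1, CAT2 (catalase, 5.79-fold, adjusted p = 0.00825) and FSD1 (iron superoxide dismutase, ratio 44.0, counting interval 14.7 to 216, adjusted p = 0.012). With the transcripts of highest total, CAT2 (adjusted p = 0.89) and FSD1 (adjusted p = 0.673) lost their calls, as did SNC1 (adjusted p = 0.0546) and RAB18 (adjusted p = 0.104) of the lists that follow. Of 20 windows of RNA silencing and DNA methylation, 1 rose and 1 fell, or 2 and 2 adjusted over the list alone. The window past AGO1, the main Argonaute of microRNAs, rose 29.8-fold (18.22 ± 4.01 against 0.527 ± 0.745 CPM, SE 0.729, adjusted p = 0.00949) on AT1G48405, and that past the DNA methyltransferase gene MET1 fell 2.50-fold (adjusted p = 0.0395). Of 16 windows of m6A writers, readers and erasers, ECT11 rose 4.02-fold (52.9 ± 8.34 against 13.2 ± 0.21 CPM, adjusted p = 0.00607) and ECT10 fell 1.75-fold (adjusted p = 0.0349), the same 1 and 1 adjusted over the list alone. Of 19 windows of the polyadenylation machinery, only AT5G60940, a subunit of the cleavage stimulation factor, rose (7.50-fold, adjusted p = 0.0111), also adjusted over the list alone. Of 14 windows of NLR immune receptors, SNC1 rose 1.78-fold (adjusted p = 0.0486) and RPP4 fell 7.20-fold (adjusted p = 0.00655), or 2 and 1 adjusted over the list alone, and both windows lie in a run. RAB18 rose at least 4.35-fold (adjusted p = 0.0327) among 3 windows of the cold and abscisic acid list (median log2 fold change 0.35, camera adjusted p = 0.492), and the window past HSP101, which lies on AT1G74300 and not on an exon of HSP101, fell 2.44-fold (adjusted p = 0.0131) among 5 of heat shock, with the same counts adjusted over the list alone. Past the root gene PHO1, a phosphate exporter, the ratio was 41.6 (13.9 to 204, adjusted p = 0.0128) among 3 root windows, with 1 higher and 1 lower adjusted over the list alone. The windows past AT5G60940, CAT2, PHO1, MET1, RPP4 and ECT10 lie on AT5G60945, AT4G35080, AT3G23420, AT5G49170, AT4G16870 and AT5G58200. That past ECT11 overlaps AT1G09800 and AT1G04733, and that past FSD1 overlaps AT4G25090 by 6 exon bases. Reads of these windows may come from those genes. No member was called of the 6 windows of salicylic acid defence, 7 of nitrate response, 7 of flowering time, 8 of the circadian clock or 5 of the auxin response, nor adjusted over the list alone. The camera adjusted p was 0.923 for all lists not given a value here. The median and mean differ in sign for the polyadenylation machinery (-0.06 and 0.08), m6A (-0.10 and 0.05), RNA silencing (-0.19 and 0.11), nitrate response (0.18 and -0.11), heat shock (-0.08 and 0.10) and root markers (-0.22 and 1.43), and the clock's median was 0.04 with a test downward. ECT10, MET1, SNC1 and RAB18 lost their calls without WT replicate 1 (adjusted p 0.0796 to 0.135) or 2 (0.068 to 0.155) and without nerd-1 replicate 1 (0.0982 to 0.181) or 2 (0.094 to 0.184). Of the 16 list members named by the rule, 11 lost it without cpsf30-1 replicate 1 (0.0518 to 0.2) and 11 without replicate 2 (0.0517 to 0.181), where RAB18 was not tested, while ECT11, APX1, PSAF and PSAD-1 kept it throughout. Of the 16, 8 lost it on the common windows without either cpsf30-1 library, and RAB18 kept it without either nerd-1 library. Without WT replicate 1 the log2 fold change of AGO1 (4.90) was 4.07 and the ratio past PHO1 was 24.98 (8.34 to 123) from 3 counts. Without WT replicate 2 both were at 0 counts in WT, so AGO1 was at least 53.7-fold and PHO1 at least 16.6-fold higher. The ratio past FSD1 was 27.4 (8.72 to 138) without cpsf30-1 replicate 1, from 3 counts in WT. That of CAT2 (2.53) was 3.13 without WT replicate 2 on the common windows.

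Some windows lie on the exons of heat shock genes and were chosen after the first values were seen. Their reads can come from the heat shock gene or from the gene upstream, and no test here separated these. Of 5 such windows, 4 rose in cpsf30-1 against WT. The window past AT1G53530 lies on the small chaperone gene HSP17.6C and rose 5.74-fold (SE 0.321, adjusted p = 0.00613), and that past VIP2 lies on HSP18.2 and rose 5.32-fold (SE 0.519, adjusted p = 0.0304). The windows on HSP70-4 (past FYD) and HSP101 (past AT1G74300) rose 2.44-fold (adjusted p = 0.0112) and 2.40-fold (adjusted p = 0.0331). The median log2 fold change was 1.88 (camera adjusted p = 0.00144, adjusted p = 0.673 with an estimated correlation). Without cpsf30-1 replicate 2 all 4 lost their calls (adjusted p 0.056 to 0.184), and all but HSP17.6C did without cpsf30-1 replicate 1 (0.059, 0.0664 and 0.08) or nerd-1 replicate 1 (0.0754 to 0.131) or 2 (0.0731 to 0.13). The windows on HSP18.2 and HSP101 also did without WT replicate 2 (0.111 and 0.112). That on HSP17.6C kept its call throughout on the common windows, and that on HSP70-4 lost it there only without cpsf30-1 replicate 2 (0.0834), while the log2 fold change on HSP18.2 (2.41) was 3.02 without WT replicate 1. Photosynthesis read in the same way had 1 higher window of 8 (camera adjusted p = 0.726).

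The comparison of nerd-1 with WT asks whether loss of a silencing factor changes reads past gene ends. Of 14151 windows, 1 rose and 5 fell (edgeR), and 1390 had an unadjusted p under 0.05, 668 higher and 722 lower. The window past AT2G11890, annotated as an adenylate cyclase, at 4804376 to 4804875 on chromosome 2, rose 6.52-fold (15.5 ± 0.66 against 2.39 ± 0.30 CPM, SD, n = 2 each, log2 fold change 2.70, SE 0.249, adjusted p = 0.0375). That window overlaps AT2G11891 on the same strand by 168 exon bases. The window past the chloride channel gene CLC-B, at 10027199 to 10027698 on chromosome 3 and on AT3G27180, fell 7.68-fold (4.04 ± 0.32 against 31.1 ± 1.68 CPM, SE 0.247, adjusted p = 0.0339). The window past KCS15, a fatty acid elongation gene, lies on AT3G52155 and fell 7.19-fold (4.73 ± 0.07 against 34.1 ± 5.45 CPM, SE 0.283, adjusted p = 0.0375). The window past the WD40 gene AT1G55680 lies on AT1G55675 and fell 6.66-fold (6.41 ± 1.71 against 42.8 ± 5.46 CPM, SE 0.273, adjusted p = 0.0375). The window past PBA1, a proteasome subunit gene, lies on AT4G31310 and fell 4.63-fold (18.995 ± 0.497 against 87.9 ± 10.06 CPM, SE 0.161, adjusted p = 0.0256), and that past the protein kinase gene AT1G73460 fell 4.60-fold (adjusted p = 0.0375). No call survived the loss of either nerd-1 library: all 6 had an adjusted p of 0.583 without nerd-1 replicate 1 and 0.557 without replicate 2. None survived without cpsf30-1 replicate 1 (adjusted p 0.137 to 0.184) or 2 (0.136 to 0.191), and AT2G11890 was also lost without WT replicate 1 (0.0662). The count was 0 in each of those 4 cases, with 589, 813, 1472 and 1502 windows at an unadjusted p under 0.05, then 6 without WT replicate 1 and 125 without WT replicate 2. Of the 125, 118 fell and 107 lay in the run on chromosome 1. Counts on the common windows were 0 in the same 4 cases (609, 716, 1433 and 1431 at an unadjusted p under 0.05), then 12 without WT replicate 1, with AT2G11890 kept, and 91 without WT replicate 2. DESeq2 called 160 windows.

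No isolated window was called in nerd-1 against WT by edgeR with all 6 libraries and its filter, where 131 were higher and 87 lower at an unadjusted p under 0.05. DESeq2 called 20 higher and 6 lower, edgeR without a filter 97 and 92, and edgeR without WT replicate 2 called 1 and 46, or 2 and 20 on the common windows. The median log2 fold change of isolated windows was 0.06 (0.04 with windows at 0 set to their bound) with a camera adjusted p of 0.273. It passed the threshold without nerd-1 replicate 2 (median 0.03, adjusted p = 0.0273) but not on the common windows (median 0.09, adjusted p = 0.0577), and was -0.06 without replicate 1, or 0 on the common windows. Counts simulated with these dispersions and 100 changed windows of each size gave 4 calls at 2-fold and 61 at 4-fold in this comparison, beside 11 false calls. Those false calls arose beside the recovered changes, which loosen the adjusted threshold, so their number cannot be set against the 6 calls observed. No list passed and no member was called in nerd-1, and the camera adjusted p of the 14 lists was 0.369 to 0.972. The lowest was shared by photosynthesis (median log2 fold change -0.36) and root markers (median 0.82). Median and mean differ in sign for RNA silencing, salicylic acid defence and heat shock (0.06 and -0.29), and both lie below 0 for NLR receptors with a test upward. Adjusted over the list alone, heat shock had 1 higher member and every other list 0.

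The comparison of cpsf30-1 with nerd-1 asks how the mutants differ. Of the 14151 windows, 1044 rose and 459 fell in cpsf30-1, with 4076 at an unadjusted p under 0.05. The window past JAL31, a jacalin lectin gene, rose at least 62.4-fold from 0 counts in nerd-1 (adjusted p = 0.0107), with 296 and 98 counts in cpsf30-1, and the next window, past AT3G16432, held near-identical counts and rose at least 62.2-fold. The window past the peroxidase gene PRXCB rose at least 40.4-fold (adjusted p = 0.0024), and that past FSD1 at least 19.9-fold (adjusted p = 0.0103). The window past AT3G29970 fell at least 9.85-fold (adjusted p = 0.0238). The neighbouring AT3G30150, AT3G30160 and AT3G30170 each fell at least 9.14-fold (adjusted p = 0.0298) with the same counts, and these windows lie in a run. The bound of JAL31 was 30.1 and 94.7-fold without cpsf30-1 replicates 1 and 2, that of AT3G16432 29.8 and 94.7-fold, and that of FSD1 12.3-fold without replicate 1. Without nerd-1 replicate 2 the bound of AT3G29970 was 6.52-fold and that of the 3 windows after it 5.84-fold. Among the 1932 isolated windows tested, 266 rose and 47 fell (odds ratio of a rise 2.35, 95% interval 2.02 to 2.73, Fisher's exact test, p = 2.33e-26). These values, and the shift of these windows given below, also depend on the filter. That odds ratio was 2.47 (exact p = 0.0502) without nerd-1 replicate 1, had no call to rest on without nerd-1 replicate 2, and was 1.49 to 1.68 without 1 of the 4 others. This ratio was, on the common windows, 2.09 to 2.69 with 1 library left out, the lowest without cpsf30-1 replicate 2 and the highest without nerd-1 replicate 2 (exact p = 0.0128). Their median log2 fold change was 0.50 (camera adjusted p = 2.12e-05, adjusted p = 0.0495 with an estimated correlation), and the median fold change of the 266 was 8.92, or 7.85 with bounds. With the filter on the libraries kept, these 1503 calls became 26 and 0 without nerd-1 replicates 1 and 2, 217 and 261 without cpsf30-1 replicates 1 and 2, and 1736 and 1508 without WT replicates 1 and 2. The 266 became 8 and 0 without nerd-1 replicates 1 and 2, and 45 and 47 without cpsf30-1 replicates 1 and 2. The calls on the common windows were 74 and 43 without nerd-1 replicates 1 and 2, 298 and 448 without cpsf30-1 replicates 1 and 2, and 2304 and 2172 without WT replicates 1 and 2, with 15, 11, 58, 77, 391 and 361 isolated windows higher in the same order. Without nerd-1 replicate 2, 2421 windows had an unadjusted p under 0.05.

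Photosynthesis also passed in cpsf30-1 against nerd-1. Of its 18 windows 6 rose and 0 fell, also adjusted over the list alone, with 17 of 18 above 0, a median log2 fold change of 0.56 and a mean of 2.26 (camera adjusted p = 0.000564, adjusted p = 0.297 with an estimated correlation). Here too 10 of the 18 were isolated, a class with a median of 0.50, so camera cannot separate the list from the class. PSAF rose 8.42-fold (adjusted p = 0.0024), PSAD-1 5.17-fold (adjusted p = 0.00384) and LHCA3 10.6-fold (adjusted p = 0.0103). Of the oxidative stress list 4 rose and 0 fell, or 4 and 1 adjusted over the list alone (median log2 fold change 1.498, camera adjusted p = 0.165), with APX1 at 31.8-fold (adjusted p = 0.00207) and CAT2 at 8.82-fold (adjusted p = 0.00518). The polyadenylation machinery had 2 higher and 0 lower, or 2 and 1 adjusted over the list alone, with AT5G60940 at 5.65-fold (adjusted p = 0.0179) and CPSF73-I, the cleaving subunit, at 2.33-fold (adjusted p = 0.025). These 2 windows lie on AT5G60945 and AT1G61000. The m6A list had 1 and 0, or 1 and 2 adjusted over the list alone, with ECT11 at 5.08-fold (adjusted p = 0.00425). RNA silencing had 1 and 1, or 2 and 1 adjusted over the list alone, with DCL1, which processes microRNA precursors, up 1.97-fold (adjusted p = 0.0343) and SUVH4 down 2.02-fold (adjusted p = 0.0383). The window past DCL1 lies on PPa1. RPP4 of the NLR list fell 12.7-fold (adjusted p = 0.00338), and the ratio of nerd-1 to cpsf30-1 past FRI, a flowering repressor gene, was 21.8 (5.66 to 186, adjusted p = 0.0322). Of the clock list LHY rose 2.103-fold (adjusted p = 0.0475), in a window that overlaps a longer transcript of LHY itself, and PCL1 fell 3.12-fold (adjusted p = 0.029), or 1 and 2 adjusted over the list alone. Of heat shock the ratio past HSFA2 was 16.9 (4.36 to 145, adjusted p = 0.0483), while the windows past HSP101 and HSP17.6C (AT1G53540) fell 2.24 and 2.11-fold (adjusted p = 0.0201 each). These 2 windows overlap other genes, AT1G74300 and AT1G53541 among them, and the windows on the exons of both genes lay above 0. Of root markers PHO1 rose 18.1-fold (adjusted p = 0.022) and SCR, of root radial patterning, fell 1.93-fold (adjusted p = 0.0321), or 1 and 2 adjusted over the list alone. Without nerd-1 replicate 1 the ratios past PHO1 and HSFA2 were 54.2 (9.54 to 2158) from 1 count and 8.20 (2.11 to 70.3) from 2 counts in nerd-1. Without nerd-1 replicate 2 the log2 fold changes of PHO1 (4.18) and LHCA3 (3.41) were 3.48 and 4.02, and HSFA2 was at 0 counts in nerd-1 and at least 5.84-fold higher in cpsf30-1. FRI was at 0 counts without cpsf30-1 replicate 1, at least 7.42-fold lower, and its ratio without replicate 2 was 10.7 (2.77 to 91.1) from 2 counts. Salicylic acid defence, nitrate response, cold and abscisic acid response and auxin response had no call, against 1 and 1, 0 and 0, 1 and 0, and 0 and 0 adjusted over the list alone. Camera adjusted p was 0.923 for auxin and 0.827 for the lists not given a value. Median and mean differ in sign for salicylic acid defence, NLR receptors, nitrate response, flowering time, the clock, heat shock (-0.21 and 0.40), cold and abscisic acid (-0.03 and 1.35), auxin and root markers (-0.95 and 0.73), and both lie above 0 for RNA silencing with a test downward. Windows on heat shock genes lay above 0 in 5 of 5, with 1 call, or 4 adjusted over the list alone (median 1.03, camera adjusted p = 0.0277, adjusted p = 0.667 with an estimated correlation). All 19 list members named by the rule lost their call without nerd-1 replicate 1 (adjusted p 0.0626 to 0.33) or 2 (0.0538 to 0.311), 14 without cpsf30-1 replicate 1 (0.0512 to 0.259) and 13 without cpsf30-1 replicate 2 (0.0536 to 0.157). FRI and HSFA2 also lost it without WT replicate 1 (0.0534 to 0.0781) or 2 (0.0589 to 0.0905). With transcripts of highest total, FSD1, CAT2, LHCA3 and LHY lost theirs (0.304, 0.446, 0.384 and 0.34). Of the 8 windows named outside the lists, the 4 higher lost it as follows: 3 without nerd-1 replicate 1 (0.115 to 0.122), 4 without nerd-1 replicate 2 (0.0523 to 0.104) and 3 without cpsf30-1 replicate 1 (0.0672 to 0.0793). The 4 lower lost it without any 1 of these nerd-1 or cpsf30-1 libraries (0.107 to 0.266), and DESeq2 did not call 3 of them (0.345). Among the common windows 16 and 17 of the 19 list members lost it without nerd-1 replicates 1 and 2, 13 and 11 without cpsf30-1 replicates 1 and 2, and 0 without a WT library. PRXCB then kept it throughout, FSD1, JAL31 and AT3G16432 lost it without either nerd-1 library and FSD1 without cpsf30-1 replicate 1 (0.0554 to 0.0856), and the 4 lower windows lost it as before (0.0781 to 0.142).

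The mutants shared 1 call against WT. The window past AT2G11890 was higher in both, with 9.89 ± 0.84 CPM in cpsf30-1 (log2 fold change 2.05, adjusted p = 0.00556). Its reads may come from AT2G11891, which it overlaps. PBA1 went in opposite directions, at 142 CPM in cpsf30-1 (log2 fold change 0.69, adjusted p = 0.0325). The number of shared higher calls by chance was 0.074, and simulation with the shared WT libraries and no effect of either mutant gave a mean of 0.28. Fold changes of the mutants correlated across windows with r = 0.431, against 0.496 in simulations that contain only the shared WT, and their covariance was 0.497 against 0.133, though windows are not independent replicates. The simulations gave neither mutant an effect and drew each window independently, so neither gap bears on a shared effect. Without WT replicate 2, WT rests on replicate 1 alone, which holds the run of 115 windows on chromosome 1. Median counts in that run were 1487 in WT replicate 1 and 9 to 16 in the mutant libraries. Lower calls shared in that fit can therefore come from the run, and do not show an effect shared by the mutants. How many shared calls lie in the run was not counted. The shared count was 0 without WT replicate 1, nerd-1 replicate 1 or 2, or cpsf30-1 replicate 1 or 2, and 114 without WT replicate 2. It was 3 and 79 on the common windows without WT replicates 1 and 2 and 0 without any 1 of the 4 others. DESeq2 gave 61.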

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

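The tests of scaling, of genomic DNA, of chance runs and of the ratio of SDs in this part, and the count of genes without an exon reading, were chosen after the result was seen. In each of 5 windows that were called in nerd-1 against WT, cpsf30-1 against nerd-1 was called too. The windows were selected by both calls, which share the low nerd-1 libraries, so the second call is not independent evidence, and cpsf30-1 against nerd-1 has 26 and 0 calls in all without nerd-1 replicates 1 and 2, or 74 and 43 on the windows tested with all 6 libraries. The log2 fold change of cpsf30-1 against nerd-1 was 3.73 past the chloride channel gene CLC-B (SE 0.253, adjusted p = 0.00138), 3.53 past KCS15 (SE 0.289, adjusted p = 0.00217), 3.01 past AT1G55680 (SE 0.275, adjusted p = 0.00274), 2.90 past PBA1 (SE 0.165, adjusted p = 0.00087) and 1.86 past AT1G73460 (SE 0.215, adjusted p = 0.00483). All 5 windows fell in nerd-1 and lie on a neighbouring gene. In transcripts that the comparisons by gene do not use, 123 genes were called in cpsf30-1 against WT only through another of their transcripts, 73 higher and 50 lower.

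More reads past gene ends in cpsf30-1, as past GUN5, D-CDES and APX1, has technical explanations that the values argue against: a scaling error would move isolated and same-strand windows alike, yet their medians differed by at least 0.525 on the log2 scale under each of 4 scalings. Each scaling moves both medians nearly alike, so the 4 are not separate tests. These medians cover only windows that passed the filter. Genomic DNA would fall on every window, yet 47.2% of all isolated windows were at 0 in both cpsf30-1 libraries, against 49.0% in WT. Higher expression of the gene itself was readable in 49 of the 301 genes, from other genes' windows on their exons, which can also hold reads of those genes: the median log2 fold change over their exons was 0.45, against 3.31 in their windows (3.12 with bounds), and 44 of 49 lay below their window. The windows were selected as called higher and the exon readings were not, so part of this gap follows from the selection. Of the 49 exon readings 9 were called higher and 0 lower, with an upper quartile of 1.15, so expression may add to some windows. How much of the typical window it accounts for cannot be told from these readings, and for the other 252 genes it stays open. A candidate explanation is transcription or cleavage past the annotated ends when CPSF30 is missing, but it rests on 2 libraries, and a difference in growth or library preparation between genotypes stays open.

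The WT libraries differed more from each other than the other pairs did. With all libraries thinned to the lowest total, the SD of the log2 difference was 0.852 in WT, against 0.562 in nerd-1 and 0.669 in cpsf30-1, which argues against depth as the cause. Without the windows in runs it was 0.718, against 0.542 and 0.650, between the bounds written beforehand. The ratio of the WT SD to the next highest fell from 1.29 to 1.104 (95% interval 1.07 to 1.13 from 2000 resamples of stretches of 50 windows), so the windows of the runs hold part of the excess and are not its whole cause. Stretches that the definition of a run misses may hold more of it, and neither this nor a biological explanation was tested.

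Runs of neighbouring windows with 1 shared minimum count, such as the 115 windows ending at CAB2 in WT replicate 1, are not chance, since windows in random order gave 0 windows in runs against 1752. Reads shared between copies of a sequence in neighbouring windows do not explain them, since 0.685% of neighbouring windows in runs share 31 bases. Copies farther apart, as at the ends of a run, were not compared. A candidate explanation is that alignments with long gaps were counted in every window that they span, which was not tested. No biological explanation was tested.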

How the results depend on the processing

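Leaving out the windows in runs, exchanging replicate numbers in the block, and leaving out a library on the 14151 windows tested with all 6 were chosen after the data were seen. Of 40 windows named by the rule in cpsf30-1 against WT, 13 were called under every alternative run, and of 1036 values 836 kept side and direction, 199 lost the call and 1 reversed. That was LHCA3, with a log2 fold change of -0.11 (adjusted p = 0.817) from its transcript with the highest total, and the cause was not tested. Of 27 in cpsf30-1 against nerd-1 and 5 in nerd-1 against WT, 0 were called under every alternative (edgeR and DESeq2), with 223 of 692 and 59 of 130 values losing the call and 0 reversing. Of 14 further windows in cpsf30-1 against WT that were named after their values were seen, 6 were called under every alternative, with 55 of 364 values losing the call, and the 1 in nerd-1 against WT was not. Of 702 values of gene lists, 577 kept side and direction, 109 changed sign without passing the test, 12 came to pass it, 4 no longer passed and 0 reversed. The isolated windows of cpsf30-1 against WT kept their shift with an estimated correlation, classes from 1000 bases, no longer isoform, library totals, no runs, each library left out, and the replicate block (median 0.530, adjusted p = 9.64e-08), which were the alternatives run for it. No fit without a filter or with the stricter filter was used to test the shift of these isolated windows. Their lower odds of a lower call reversed to an odds ratio of 1.13 without WT replicate 2 and 1.03 without nerd-1 replicate 1, and ranged from 0.410 to 1.13 with 1 library left out. On the 14151 windows it reversed without WT replicate 2 (1.11), nerd-1 replicate 1 (1.04) or 2 (1.05) and cpsf30-1 replicate 1 (1.05).

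At an adjusted p under 0.01, calls were 345 in cpsf30-1 against WT, 225 in cpsf30-1 against nerd-1 and 0 in nerd-1 against WT, with 77 and 50 isolated higher for the cpsf30-1 comparisons. Without a filter they were 2807, 3021 and 640, with 626, 598 and 97 isolated higher, and many windows near 0 were added. From only the 4 libraries compared they were 893, 2287 and 0 (1362 at an unadjusted p under 0.05). With the replicate block they were 592, 409 and 0 (942 at an unadjusted p under 0.05), with 136 and 88 isolated higher. The crossed block gave 2440 in cpsf30-1 against nerd-1, 17 in nerd-1 against WT and 4 shared by the mutants. DESeq2 gave 160 in nerd-1 against WT, 20 isolated higher and 61 shared. Library totals gave 2, all deposited transcripts 10, and leaving out runs 12 in nerd-1 against WT. All transcripts gave 493 and 432 isolated higher for cpsf30-1 against WT and against nerd-1. Shared calls were 0 with the replicate block and 2 without runs. Gene lists passing were 0 with an estimated correlation and 3 with fry, for each cpsf30-1 comparison. Where no reason is given, the cause was not tested.

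Leaving out 1 library leaves a lone sample that is assumed to vary like the other groups, and lets the filter pass 15311 to 15896 windows. Without WT replicate 2 that lone sample is WT replicate 1, which holds the longest run on chromosome 1. Lower calls in either mutant, and calls shared by them, can then come from this run. On the 14151 windows tested with all 6 libraries the windows named by the rule lost 56 calls instead of 96 in cpsf30-1 against WT, and 80 instead of 95 in cpsf30-1 against nerd-1. Calls there ranged from 479 to 1159, from 43 to 2304 and from 0 to 91 in cpsf30-1 against WT, cpsf30-1 against nerd-1 and nerd-1 against WT, isolated windows called higher from 94 to 248, from 11 to 391 and from 0 to 2, shared calls from 0 to 79, and the median of isolated windows in nerd-1 from 0 to 0.215. With the filter on the 5 libraries kept, calls ranged from 236 (without cpsf30-1 replicate 2) to 924 (without WT replicate 2) in cpsf30-1 against WT, from 0 (without nerd-1 replicate 2) to 1736 (without WT replicate 1) in cpsf30-1 against nerd-1, and from 0 (without either library of nerd-1 or cpsf30-1) to 125 (without WT replicate 2) in nerd-1 against WT. Isolated windows called higher ranged from 49 to 145, from 0 to 268 and from 0 to 1. Shared calls ranged from 0 to 114, the median of isolated windows in nerd-1 from -0.055 to 0.20, and gene lists passing from 1 to 2 in each cpsf30-1 comparison. On the 14151 windows photosynthesis was joined only by oxidative stress in cpsf30-1 against nerd-1, without nerd-1 replicate 1. With the filter on the libraries kept it was joined without cpsf30-1 replicate 1 by oxidative stress in both, without WT replicate 1 by oxidative stress in cpsf30-1 against WT, without nerd-1 replicate 1 by oxidative stress in cpsf30-1 against nerd-1, and without cpsf30-1 replicate 2 by cold and abscisic acid response in cpsf30-1 against WT.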

Other observations

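Only the shares for next windows that are not isolated were chosen after a result of this part was seen. Isolated windows with more reads in cpsf30-1 often lie past genes of chloroplast proteins. Of the 213 higher windows whose gene has a location note, 82 were noted as chloroplast, or 38.5% against 16.8% of the other windows. Random lists matched on the mean CPM of the window over all libraries had a median of 49 and a 95th percentile of 58. Expression of the upstream gene was not matched, so it may lie behind the excess. The permutation p was 1e-04, the smallest that 10000 lists can give (adjusted 7e-04 over 7 terms). Mitochondrion was noted for 18, against a random median of 9 (permutation p = 0.0012, adjusted 0.0042). An unknown location was noted for fewer, 24 against a random median of 39, or 11.3% against 19.9% of the other windows (lower-side permutation p = 0.0018, not adjusted). GUN5 of chlorophyll synthesis, the photosystem I gene LHCA2 and RBCS3B of Rubisco are among the genes with higher windows. Whether nuclear genes of chloroplast proteins differ in their end signals was not tested.

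Reads that run on could reach the next gene on the same strand. The window past that next gene was higher after 16 of 143 higher isolated windows and after 71 of 850 others, 11.2% and 8.35% (odds ratio 1.38, 95% interval 0.726 to 2.50, Fisher's exact p = 0.264). Where the next window is not isolated the shares were 5.36% and 7.26%. The bounds written beforehand counted an odds ratio under 1.5 or an exact p of 0.05 or more against this, and both were met, but the interval reaches well past 1.5 and a missed threshold decides nothing, so it stays open. AATAAA in the last 50 bases of the transcript was present in 22 of 301 higher and 148 of 1631 other isolated windows, 7.31% and 9.07% (odds ratio 0.790, 95% interval 0.472 to 1.27, Fisher's exact p = 0.376). The bounds written beforehand counted an odds ratio between 0.8 and its inverse, or an exact p of 0.05 or more against a difference. The odds ratio lies outside that range and only the p met its bound, which decides nothing, and the interval reaches past both ends of the range, so this stays open too.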
